A study of Homo sapiens with 24 samples.

How the data were processed

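Gene expression was measured by RNA sequencing of polyA RNA in VCaP, LNCaP and SW13 cells, in 24 libraries and 12 groups of 2. Per the labels' protocols, cells were exposed to lentivirus for 48 h and selected for 8 (VCaP), 4 (LNCaP) or 2 (SW13) days, RNA was made with RNeasy kits, and 75 base single-end reads were made on a NextSeq 500. The duplicates came from independent infection, selection and culture, so the replicate numbers were not read as pairs. The titles call the SW13 control construct GFP while the protocol text names luciferase, and the title's name is used here.

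The authors deposited per library a table of genes with read counts, a gene length and an RPKM value. The deposited counts are whole numbers with a different total in each library, and they alone were tested. The deposited RPKM values equal the counts scaled by the library total and by the deposited gene length, the other column, and were used only to learn what the columns hold. STAR 2.3.1 and the genome build hg19 were named per the submitters' processing notes, and the counting program, annotation and strand setting are not given in the sources used here. Gene positions were not used here. The tables held 26346 genes, and 25240 symbols matched a RefSeq gene table.

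Counts were analysed with R 4.3.3, edgeR 4.0.16 and limma 3.58.1, and tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Each cell line was fitted on its own, with all of its groups in 1 fit, TMM scaling (factors 0.938 to 1.077 in VCaP, 0.983 to 1.014 in LNCaP, 0.91 to 1.065 in SW13) and filterByExpr by group. The common biological coefficient of variation was 0.0394, 0.0608 and 0.0571, with 3, 3 and 6 residual degrees of freedom. Contrasts were tested with edgeR's quasi-likelihood F test, two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. There were 12 comparisons of groups, 3 differences between ERG effects in SW13 and 4 overlaps of gene sets. Gene lists, 23 with 452 members of which 439 were found (3 by another symbol), were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of 1 comparison, and again with an estimated correlation. The 13 mitochondrially encoded genes were absent, leaving 22 lists. Of 330 list tests 91 were called, 14 also with an estimated correlation and 77 not. All 14 were in SW13, with 6 residual degrees of freedom against 3 in VCaP and LNCaP, so losses there need not mark weaker lists. The 14 were the ETS family for ERG beside GFP (adjusted p = 0.209 without ERG) and interferon-stimulated, endothelial and basal genes for ERG beside BRG1. For BRG1, interferon-stimulated, BRG1-restored, basal and mesenchymal genes held against GFP and BRG1-K785R, and invasion and neuroendocrine genes against GFP.

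Comparisons, tests, lists and most alternatives were chosen before the data were examined. So was the rule for named genes, which took the target genes, the 8 largest rises and 8 largest falls (4 and 4 in secondary comparisons and differences of effects) among called genes with a mean of at least 5 CPM and no overlap between groups, up to 4 called members per list and 16 per comparison by smallest adjusted p, and 6 genes per overlap. Clone, LOC, pseudogene, small RNA and open reading frame names were left out, with FAM and KIAA names kept. A few genes that the rule took are not reported here. Where a group had 0 reads, the fold was bounded with a floor of 3 counts per library, and with 1 to 3 reads a ratio with its 95% counting interval was given. A further list of nuclear-retained RNAs was written for a test in the closing section.

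Replicates varied beyond counting error, with a chi-square per degree of freedom of 2.48 to 15.87 between the libraries of a group. The fits were tested on simulated data with known changes. At true folds of 1.5, 2 and 4, 89.6%, 86.6% and 100% of changed genes were recovered for VCaP shERG, 58.2%, 80% and 87.9% for LNCaP ERG, 76.6%, 74.2% and 100% for SW13 ERG beside BRG1, and 50.7%, 71.2% and 89.2% for the difference between ERG effects with BRG1 and GFP. False calls were 18 of 202, 25 of 174, 5 of 169 and 5 of 144. For VCaP and LNCaP that exceeds the nominal share. Far fewer genes changed than were called in the data, so the real share is open.

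Alternatives were RLE scaling, no filter on low counts, DESeq2 1.42.0, only the compared groups in the fit, the replicate number as a block, leaving out each library in turn and, chosen after seeing the data, library totals as the scale and a SW13 fit without both BRG1-K785R Empty libraries. No group was large enough for a test of outlying samples or of other splits of the samples.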

Results

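RNA sequencing had been done on 24 libraries from 3 human cell lines, in 12 groups of 2 libraries each. VCaP and LNCaP are prostate cancer lines, and SW13 is an adrenal carcinoma line. VCaP cells, whose ERG gene is driven by the TMPRSS2 fusion, carried shRNAs against ERG or ARID1A or a control (shCt). LNCaP cells carried ERG, ETV1 or an empty vector, and SW13 cells carried ERG or an empty vector beside BRG1 (the product of SMARCA4), its ATPase mutant BRG1-K785R or a GFP control. Libraries held 19754265 to 41996681 counted reads, and 16791 (VCaP), 16993 (LNCaP) and 17018 (SW13) genes were tested. Levels below are mean CPM (counts scaled to a common library total) ± SD (n = 2 per group). Log2 changes carry an approximate standard error (SE), which few reads can make too small. Unless another test is named, adjusted p values are from edgeR's two-sided quasi-likelihood test (Benjamini-Hochberg), called at 0.05.

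The targeted genes followed the labels in every library. In VCaP, ERG stood at 363 ± 14.6 CPM with shCt, 78.9 ± 5.18 with shERG and 243 ± 3.91 with shARID1A. ARID1A, the large AT-rich interaction subunit of the BAF chromatin remodeler, stood at 265 ± 3.53, 225 ± 10.3 and 74.5 ± 2.07 CPM in the same order. In LNCaP, ERG stood at 0.444 ± 0.241 CPM with the empty vector and 973 ± 28.7 with the ERG construct. ETV1, another ETS factor, was already abundant there at 573 ± 18.1 CPM and reached 3740 ± 103 with its construct. In SW13, ERG was read at 1530 ± 87.2 CPM with GFP, 1540 ± 53.5 with BRG1-K785R and 1950 ± 206 with BRG1 when the ERG construct was present. Without it, ERG reads were 1 and 2 in the GFP libraries, 0 in both BRG1-K785R libraries and 6 and 1 in the BRG1 libraries. SMARCA4 stood at 29.5 ± 3.57 CPM with GFP and at 2050 ± 17.4 with BRG1 or 2310 ± 120 with BRG1-K785R. The SMARCA4 reads of construct and chromosome cannot be separated in these counts.

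**Figure D1:**
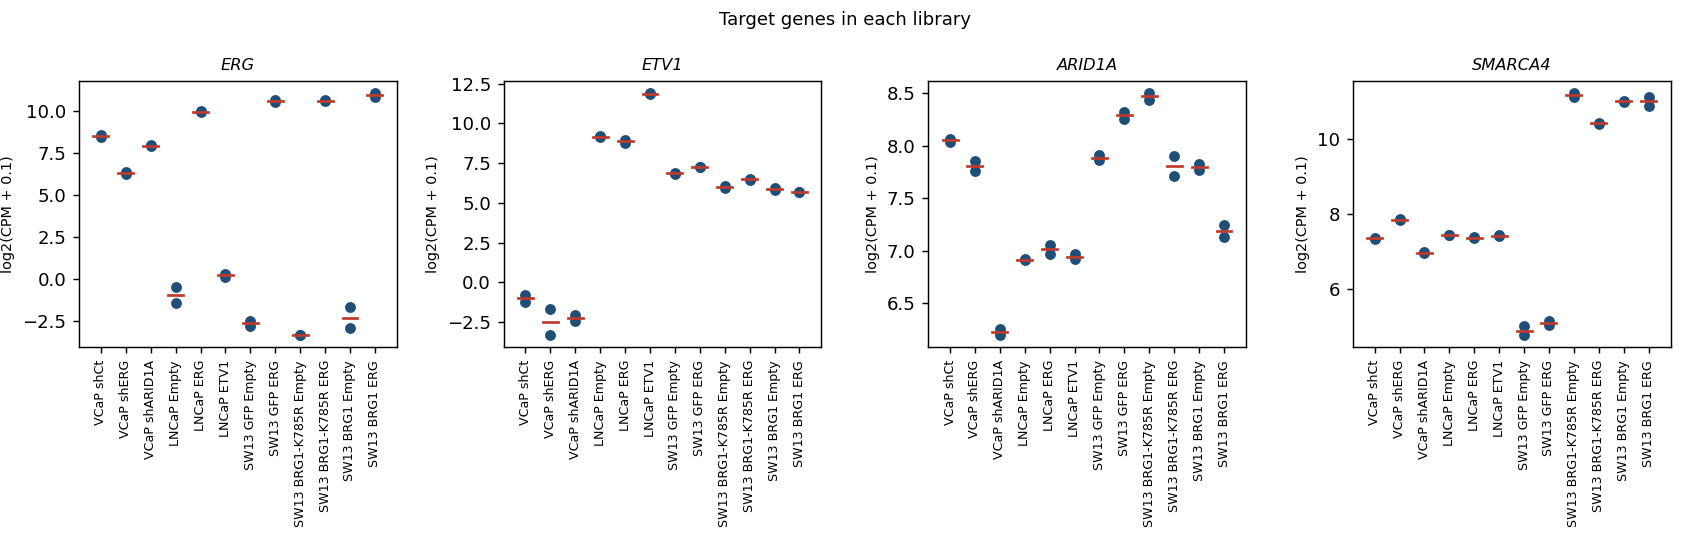
Levels of ERG, ETV1, ARID1A and SMARCA4 in each library. Each point is 1 library, on the scale log2(CPM + 0.1), and the red line is the mean of the log values of a group (n = 2).

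The first question was which VCaP genes change with the fusion-driven ERG. With shERG, ERG was 4.61-fold lower (log2 change -2.2 ± 0.05, adjusted p = 3.51e-19). REG4, which encodes a secreted lectin, fell 34.8-fold, from 2620 ± 54.3 to 75.2 ± 8.82 CPM (-5.12 ± 0.07, adjusted p = 9.66e-23). The trefoil peptide gene TFF1 fell 30.3-fold (132 to 4.34 CPM), TSPAN1, a tetraspanin, 29.5-fold (144 to 4.92 CPM), and the calcium-binding protein gene S100P 23.6-fold. Other large falls were in CYP4F12 (45.2-fold), ADAMTSL1 (39.6-fold), SEMG2 (35-fold, a gene with a near-identical neighbour, so that its reads are uncertain) and CEACAM20 (230-fold by the fit, with 3 and 1 reads left). DIO2, the deiodinase that activates thyroid hormone, rose 83.6-fold (6.39 ± 0.23). LRRN3 rose 22.8-fold, INHBA, which encodes an activin subunit, 16.3-fold, BNC2 16.1-fold, ALS2CL 11.1-fold, DOCK3 9.51-fold, the lipid carrier APOE 8.89-fold (3.15 ± 0.13) and WSCD1 8.76-fold.

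The cell cycle genes fell together with shERG. All 28 tested members fell, also when adjusted over the list alone, with a median log2 change of -1.35. Examples were the proliferation marker MKI67 (-2.08 ± 0.06), the S-phase factor E2F1 (-3.24 ± 0.09), RRM2, a ribonucleotide reductase subunit (-2.18 ± 0.08), and PCNA (-1.54 ± 0.05). The camera test gave an adjusted p of 7.85e-23 for this list, and adjusted p = 0.497 with an estimated correlation. Of 22 luminal epithelial genes, 3 rose, 17 fell and 2 were not called, with equal counts when adjusted over the list alone. The keratins KRT18 (-1.49 ± 0.05) and KRT8 (-1.5 ± 0.05), the tight junction gene CLDN4 (-1.32 ± 0.05) and the splicing regulator ESRP1 (-1.25 ± 0.05) were among them (camera adjusted p = 9.27e-07, adjusted p = 0.344 with an estimated correlation). Genes reported high in ERG-positive prostate tumours gave 2 rises, 12 falls and 3 uncalled of 17 tested, as also when adjusted over the list alone, among them NCALD (-1.93 ± 0.06), CRISP3 (-1.83 ± 0.07), PLA1A (-1.5 ± 0.07) and HLA-DMB (-1.31 ± 0.07). The camera adjusted p was 0.000156, and 0.344 was the adjusted p with an estimated correlation.

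Androgen receptor targets split in VCaP with shERG: 8 rose, 17 fell and 3 were not called of 28, or 8 and 18 when adjusted over the list alone. KLK3, which encodes prostate-specific antigen, fell from 996 to 230 CPM (-2.12 ± 0.06), beside SPDEF (-2.14), the ion channel gene TRPM8 (-1.84) and SLC45A3 (-1.2 ± 0.06). Camera called the list lower (adjusted p = 0.00286, adjusted p = 0.628 with an estimated correlation). The ETS family, which includes the targeted ERG, gave 3 rises, 10 falls and 4 uncalled of 17, alike when adjusted over the list alone (median -0.51, camera adjusted p = 0.00888, adjusted p = 0.344 with an estimated correlation, adjusted p = 0.0888 with no filter on low counts, 0.12 without ERG). Of 14 basal epithelial genes 2 rose, 9 fell and 3 were not called, again with equal counts adjusted over the list alone (median -0.91). That camera call (adjusted p = 0.0326) had an adjusted p = 0.673 with an estimated correlation, 0.0551 with no filter and 0.0507 without the shCt 2 library. Mesenchymal and matrix genes gave 11 rises, 2 falls and 5 uncalled of 18, with a median of 0.68, and were not called by camera (adjusted p = 0.101). Among BAF subunits 9 rose, 12 fell and 7 were not called (median -0.11, while the uncalled test pointed up, adjusted p = 0.819). SMARCA4 itself rose (0.49 ± 0.04), SMARCA2, the alternative ATPase, fell (-0.55 ± 0.05), and ARID1A fell slightly (-0.24 ± 0.05, adjusted p = 9.86e-05; -0.14 without shERG 1; with library totals as the scale -0.06, adjusted p = 0.255).

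In all, 11203 genes were called with shERG, 4923 higher and 6280 lower, of which 1071 and 1840 changed at least 2-fold. The share that rose was 43.9% and became 60.5% when library totals replaced the scaling factors, a shift of 0.183 in the median log2 change of all genes. Small changes in this comparison therefore hold relative to that shift. Medians and means differed in sign for WNT pathway genes (-0.04 and 0.24, with a test that pointed down, adjusted p = 0.583) and interferon-stimulated genes (0.16 and -0.04).

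The next question was what shARID1A does. With shARID1A, ARID1A was 3.57-fold lower (-1.83 ± 0.05, adjusted p = 4.17e-18), and ERG was 1.49-fold lower (-0.58 ± 0.05, adjusted p = 7.31e-10). The long noncoding RNA PCAT1 fell 45.3-fold (-5.5 ± 0.15), CEACAM20 41.2-fold, CAMKV 34.7-fold, FAM111B 23.7-fold, DDN 21.7-fold, SI, the gene of sucrase-isomaltase, 20.6-fold, and the replication and repair genes MCM10 and EXO1 20.4-fold and 19.1-fold. FOSB, an AP-1 gene, rose 36.5-fold, CYP4Z1 28.7-fold, NRP2, a semaphorin co-receptor, 26-fold (4.7 ± 0.2) and the zinc transporter gene SLC39A2 26-fold (12.1 to 315 CPM). The cystatin genes CST4 (51-fold), CST1 (37.9-fold) and CST2 (33.1-fold) also rose, but they resemble one another closely enough to share reads. SMARCA4 fell (-0.38 ± 0.05), and SMARCA2 was at -0.01 (adjusted p = 0.92).

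The cell cycle list was again lower throughout with shARID1A, 28 of 28 members, also when adjusted over the list alone (median -2.76). MKI67 fell by 3.21 ± 0.07 on the log2 scale, RRM2 by 3.91 ± 0.09, and the replicative helicase genes MCM4 and MCM7 by 2.87 ± 0.06 and 1.89 ± 0.05 (camera adjusted p = 5.1e-58, adjusted p = 0.243 with an estimated correlation). AP-1 and immediate early genes gave 11 rises, 3 falls and 1 uncalled of 15, alike when adjusted over the list alone, with EGR1 (3.53 ± 0.07), FOS (3.85 ± 0.09), JUN (1.95 ± 0.05) and JUNB (1.41 ± 0.05). Their camera adjusted p was 2.7e-12, with an adjusted p = 0.0957 with an estimated correlation. Cholesterol synthesis genes gave 14 rises, 1 fall and 4 uncalled of 19, alike when adjusted over the list alone. SC5D (1.71 ± 0.06), HMGCS1 (1.21 ± 0.06), the feedback regulator INSIG1 (1.37 ± 0.07) and LSS (0.67 ± 0.04) rose (camera adjusted p = 3.77e-05, adjusted p = 0.449 with an estimated correlation). Luminal genes gave 12 rises, 6 falls and 4 uncalled of 22, or 13 and 6 adjusted over the list alone, with CLDN4 (2.03 ± 0.05), CLDN3 (1.64), ELF3 (1.16) and the cadherin CDH1 (0.94 ± 0.04) higher. The camera adjusted p was 0.000856, and adjusted p = 0.29 with an estimated correlation. Genes reported high in ERG-positive tumours gave 2 rises, 13 falls and 2 uncalled of 17. Replication-dependent histones gave 9 rises, 1 fall and 2 uncalled of 12. Both were alike adjusted over the list alone. Camera's adjusted p was 0.00294 and 0.00553 in this order, and 0.243 for each with an estimated correlation. The histones share reads, and only polyA RNA was read. Histone synthesis was not measured here or below. Genes reported restored by BRG1 in BRG1-deficient lines gave 7 rises, 0 falls and 2 uncalled of 9, alike adjusted over the list alone (camera adjusted p = 0.0151, adjusted p = 0.268 with an estimated correlation). Over all genes, 5521 rose and 5575 fell with shARID1A, 1421 and 1628 of them at least 2-fold, and the share that rose was 49.8%, or 55.7% with library totals.

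**Figure D2:**
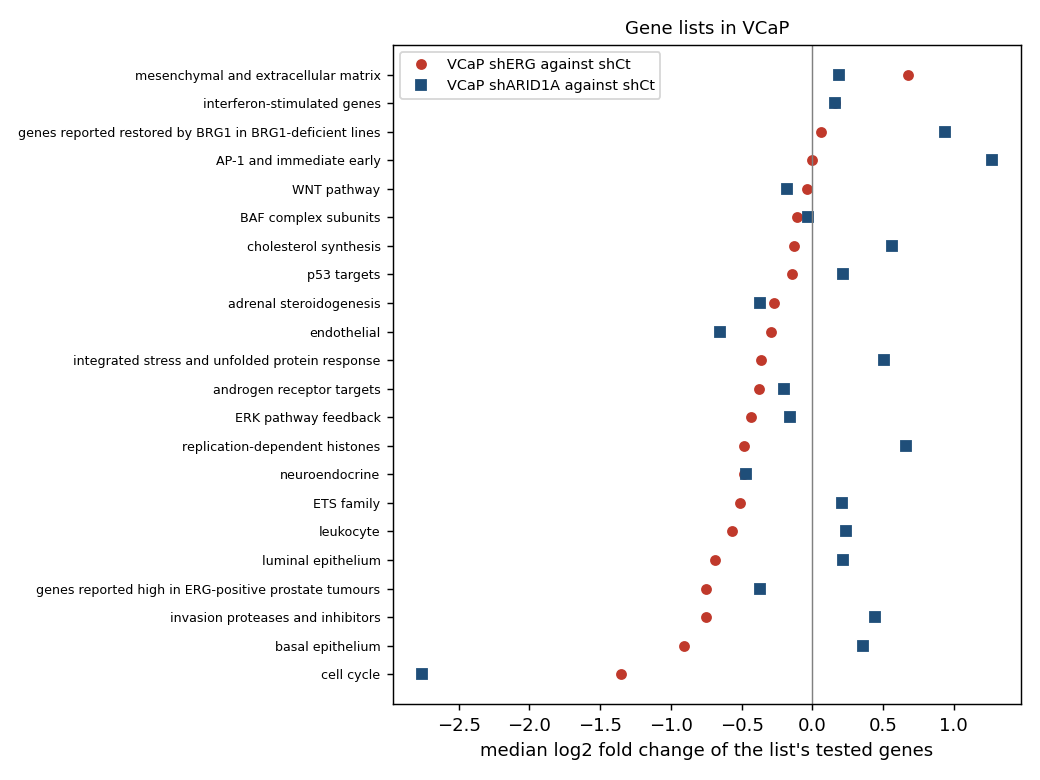
Median log2 change of the tested members of 22 gene lists in VCaP, for shERG (red circles) and shARID1A (blue squares) against shCt. Medians under library totals are higher by the shifts in all genes of 0.183 and 0.067, which is more than the distance from 0 of some points near the line.

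Set directly against each other, shARID1A and shERG differed in 12262 genes, 6186 higher with shARID1A and 6076 lower, of which 2411 and 1726 at least 2-fold. The share higher was 50.4%, and 42.4% with library totals. ERG was 1.63 ± 0.05 higher and ARID1A lower (-1.59 ± 0.05) with shARID1A. SEMG2 was 202-fold, CST4 196-fold and the chemokine gene CXCL12 171-fold higher with shARID1A. DIO2 was 107-fold, PCAT1 101-fold, SI 64-fold and BCHE, the gene of butyrylcholinesterase, 39.1-fold lower. Luminal genes gave 18 higher, 3 lower and 1 uncalled of 22, alike adjusted over the list alone: CLDN4 by 3.34, CLDN3 by 2.46, ELF3 by 2.24 and KRT8 by 2.1, each ± 0.05. By camera the adjusted p was 3.84e-11, and adjusted p = 0.188 with an estimated correlation. Cell cycle genes were lower in 26 of 28 and higher in 1, or 26 and 2 adjusted over the list alone, with BIRC5 at -2.17 ± 0.1, BUB1B at -2.13, TOP2A at -1.51 and MCM4 at -1.33. Camera gave it an adjusted p of 1.96e-09, and adjusted p = 0.548 with an estimated correlation. AP-1 and immediate early genes (13 higher, 0 lower, 2 uncalled of 15, alike adjusted over the list alone) had a camera adjusted p of 1.14e-08, and adjusted p = 0.166 with an estimated correlation.

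Further lists were called higher with shARID1A than with shERG. Cholesterol synthesis gave 15 higher and 2 lower (median 0.69, camera adjusted p = 0.000341, adjusted p = 0.555 with an estimated correlation), and the ETS family, ERG included, 11 higher and 2 lower, or 12 and 2 adjusted over the list alone (camera adjusted p = 0.000541, adjusted p = 0.188 with an estimated correlation). Histones gave 10 higher and 1 lower (median 1.02, camera adjusted p = 0.00211, adjusted p = 0.227 with an estimated correlation), and stress response genes 15 higher and 3 lower of 18 (median 0.73, camera adjusted p = 0.00273, adjusted p = 0.476 with an estimated correlation). The BRG1-restored genes gave 6 higher and 1 lower, or 6 and 2 adjusted over the list alone, with an adjusted p = 0.0125 by camera, 0.264 as the adjusted p with an estimated correlation and 0.0827 with no filter. Library totals moved the median of all genes by -0.116 in this comparison.

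Many genes moved the same way with both shRNAs: 2085 rose and 2935 fell with both (1618.7 and 2085.1 for independent lists). Genes that rose with shERG and fell with shARID1A numbered 1094 (1634.5 for independent lists), and those that fell and then rose 1828 (2064.9). Falls with shERG and shARID1A included SCUBE2 (-3.57 and -3.68), MCCC2 (-2.53 and -2.69), ITM2A (-1.83 and -1.74), the neurosecretory gene VGF (-2.46 and -3.62), PPFIA2 (-1.93 and -2.02) and MKI67 (-2.08 and -3.21). Part of any excess may come from the shared shCt libraries or the lower ERG with both. With 1 shRNA group per target, other shRNA effects stay open. With shCt 1 for shERG and shCt 2 for shARID1A, 1626 rose and 2625 fell with both (1233.7 and 1748.5 for independent lists). With these swapped it was 1661 and 2533 (1285.3 and 1759.4). In 20 simulations of unchanged groups with shared controls, at most 1 gene was called in both (mean 0.2), too few to gauge the controls' part. Across genes, which are not independent replicates, r was 0.24 (rho 0.24) against 0.52 ± 0.013 (SD) simulated. The covariance of log2 changes was 0.218 against 0.0168.

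LNCaP cells carry no such fusion of ERG, and the question there was what an added ERG does. REG4 rose 62.2-fold with ERG, from 1.12 to 69.5 CPM (5.96 ± 0.16), the lipase gene LIPG 97.2-fold, DIO3, the deiodinase that inactivates thyroid hormone, 31.5-fold, the laminin gene LAMB3 21.8-fold (4.45 ± 0.27), the adhesion receptor gene ADGRF5 21.5-fold and ARHGDIB 20.6-fold. KRT75 had 3 reads in the Empty libraries together, and its ratio was 279 (95% interval 95 to 1350). ERG itself was 2160-fold higher (11.07 ± 0.13, adjusted p = 3.97e-10). Falls were led by S100A6 (36.2-fold), AKR1B1 (28-fold), TGFBI and ANXA2 (21-fold each), the transglutaminase gene TGM2 (20-fold), the galectin gene LGALS1 (11.6-fold), IGFBP4 (11-fold) and the tropomyosin gene TPM2 (6.23-fold). These genes were low and uneven in the Empty libraries: S100A6 stood at 11.3 ± 5.33 CPM, AKR1B1 at 9.65 ± 7.87, TGFBI at 15.7 ± 5.38, ANXA2 at 16.6 ± 4.58, TGM2 at 10.3 ± 11.8, LGALS1 at 10.2 ± 3.26, IGFBP4 at 9.53 ± 9.2 and TPM2 at 9.36 ± 5.68. ANXA2 also has processed copies elsewhere in the genome. Without the ERG 1 library, TGM2 (-4, adjusted p = 0.0775) and IGFBP4 (-3.13, adjusted p = 0.0592) were not called and the fitted log2 change of TGFBI was -7.79, and TGM2 stood at -1.94 without Empty 2 and IGFBP4 at -1.8 without Empty 1. ETV1 fell by 0.28 ± 0.06 on the log2 scale (adjusted p = 0.00804, 0.0677 without Empty 2), and SMARCA2 rose by 0.3 ± 0.07 (adjusted p = 0.00935, 0.0504 without Empty 1 and 0.0868 without Empty 2).

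Cholesterol synthesis was the list with the most uniform change in LNCaP with ERG: 19 of 19 genes rose, also when adjusted over the list alone (median 1.14). HMGCS1, an early enzyme of the pathway, rose by 2.41 ± 0.14 (99.9 to 533 ± 121 CPM), FDFT1, the squalene synthase gene, by 1.57 ± 0.07, the lipid transfer gene STARD4 by 1.27 ± 0.07 and MSMO1 by 1.62 ± 0.09. Its camera adjusted p was 6.52e-39, and adjusted p = 0.271 with an estimated correlation. Androgen receptor targets gave 2 rises, 13 falls and 13 uncalled of 28, or 3 and 13 adjusted over the list alone. MAF fell by 1.79 ± 0.11, SORD by 0.66 ± 0.05 and ALDH1A3 by 0.72 ± 0.06 on the log2 scale. The list had a camera adjusted p of 0.00183, and adjusted p = 0.405 with an estimated correlation. Genes reported high in ERG-positive tumours gave 8 rises, 4 falls and 6 uncalled of 18, or 10 and 4 adjusted over the list alone (median 0.37, camera adjusted p = 0.00495, adjusted p = 0.286 with an estimated correlation). Interferon-stimulated genes gave 13 rises, 1 fall and 9 uncalled of 23 on either adjustment, all genes or adjusted over the list alone (camera adjusted p = 0.00569, adjusted p = 0.405 with an estimated correlation). The stress response list gave 8 rises, 5 falls and 5 uncalled of 18, alike adjusted over the list alone (camera adjusted p = 0.0192, adjusted p = 0.405 with an estimated correlation).

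Several camera calls in LNCaP with ERG rested on few members or few libraries. WNT pathway genes gave 3 rises, 2 falls and 7 uncalled of 12, or 4 and 2 adjusted over the list alone (camera adjusted p = 0.00356, adjusted p = 0.271 with an estimated correlation, 0.122 with no filter). The receptor FZD4 rose by 2.48 ± 0.06, RNF43, which encodes a brake on WNT receptors, by 0.91 ± 0.07 and TCF7L2 by 0.42 ± 0.08. WNT5A fell by 0.9 ± 0.23 on the log2 scale (adjusted p = 0.0171), a call lost without Empty 1 (0.12), ERG 1 (0.0697) or ERG 2 (0.0682). The ETS family, transgene ERG and native ETV1 included, gave 2 rises, 2 falls and 17 uncalled of 21, alike adjusted over the list alone, among them ETV6 (0.55 ± 0.09) and EHF (-0.28 ± 0.04), with a median of 0.03 and a mean of 0.38. The camera adjusted p was 0.000275, and adjusted p = 0.271 with an estimated correlation, 0.673 with no filter, and 0.949 and downward without ERG and ETV1. ERK feedback genes gave 6 rises, 4 falls and 8 uncalled of 18, alike adjusted over the list alone. Their median was -0.08 and their mean 0.12, and camera pointed up (adjusted p = 0.00638, adjusted p = 0.405 with an estimated correlation, 0.0665 with no filter, 0.15 without Empty 1). Of 15 AP-1 and immediate early genes 7 rose, 1 fell and 7 were uncalled, or 8 and 2 adjusted over the list alone (camera adjusted p = 0.00681, adjusted p = 0.375 with an estimated correlation, 0.0716 without Empty 1). Of 14 endothelial genes 3 rose, 1 fell and 10 were uncalled, or 5 and 1 adjusted over the list alone (camera adjusted p = 0.013, adjusted p = 0.405 with an estimated correlation, 0.0665 with no filter, 0.15 without Empty 1). Cell cycle genes gave 0 rises, 3 falls and 25 uncalled, or 0 and 0 adjusted over the list alone (median -0.32, camera adjusted p = 0.0157, adjusted p = 0.825 with an estimated correlation, 0.0642 without Empty 2 and 0.858 without ERG 1).

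With ERG, 5045 LNCaP genes were called, 2611 higher and 2434 lower, of which 547 and 349 changed at least 2-fold. The count was 2632 without Empty 1 and 2939 without Empty 2. The share that rose was 51.8%, and 49.6% with library totals.

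ETV1 was asked about in the same way. It rose 6.53-fold over its level with the empty vector (2.71 ± 0.06, adjusted p = 4.04e-08). MGP, which encodes an inhibitor of calcification, rose 306-fold, from 0.752 to 230 ± 20.4 CPM (8.26 ± 0.13, adjusted p = 2.94e-09), GRAMD1B 91.5-fold, MYH13 36.1-fold, REG4 26.2-fold, FAM131B 25.6-fold and the corepressor gene TLE4 20.3-fold. TCN1, a vitamin B12 carrier gene, had 0 reads in the Empty libraries and 15.2 ± 2.72 CPM with ETV1, at least 208-fold higher against a floor of 3 counts per library. Floors and intervals of this kind cover counting error only. The cytokine gene IL33 rose 20.1-fold (4.33 ± 0.65), a call that DESeq2 did not make (adjusted p = 0.159) and a fitted value of 12.72 without Empty 2. ERG moved from 0.444 to 1.09 CPM (1.28 ± 0.29, adjusted p = 0.0115; 0.82 and adjusted p = 0.0602 without Empty 1, 1.98 without Empty 2, and adjusted p = 0.0851 without ETV1 2). TGFBI fell 57.6-fold, TGM2 39.9-fold, LGALS1 32.7-fold, ANXA2 26.4-fold, AKR1B1 15.3-fold, the lysyl oxidase gene LOXL2 8.47-fold and PEG10 8.31-fold, and S100A6, with 3 reads left, by a ratio of 292 (95% interval 99.6 to 1420). As above, these genes were uneven in the Empty libraries, with LOXL2 at 16.8 ± 14.5 and PEG10 at 11.6 ± 13.1 CPM. TGM2 was not called without ETV1 1 (0.0711) or ETV1 2 (0.0724), AKR1B1 and LOXL2 without ETV1 2 (0.0582 and 0.0712), and PEG10 without Empty 1 (-0.74, adjusted p = 0.129), ETV1 1 (0.149) or ETV1 2 (0.161). TGM2 stood at -2.94 without Empty 2 and LOXL2 at -1.72 without Empty 1.

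Androgen receptor targets were mostly lower with ETV1: 3 rose, 19 fell and 6 were uncalled of 28, or 3 and 23 adjusted over the list alone (median -0.51). MAF fell by 2.25 ± 0.11, HERC3 by 1.43 ± 0.07, SORD by 0.77 ± 0.05 and ALDH1A3 by 0.96 ± 0.06 on the log2 scale (camera adjusted p = 4.19e-20, adjusted p = 0.621 with an estimated correlation). Cholesterol synthesis genes gave 13 rises, 0 falls and 6 uncalled of 19, alike adjusted over the list alone (median 0.39), among them FDFT1 (0.75 ± 0.07), FDPS (0.78 ± 0.1), STARD4 (0.59 ± 0.07) and DHCR7 (0.57 ± 0.07). Camera called that list with an adjusted p of 2.99e-07, and the adjusted p was 0.621 with an estimated correlation. Of 18 ERK feedback genes 6 rose, 5 fell and 7 were uncalled, alike adjusted over the list alone. The ERK phosphatase genes DUSP6 (3.55 ± 0.13) and DUSP4 (1.25 ± 0.1) and the inhibitors SPRY1 (1.13 ± 0.05) and SPRED2 (1.1 ± 0.09) rose. The median (-0.07) and mean (-0.02) of this list stood against a camera test that pointed up (adjusted p = 0.0021, adjusted p = 0.621 with an estimated correlation, 0.204 with no filter, 0.186 without Empty 1). AP-1 and immediate early genes gave 6 rises, 1 fall and 8 uncalled of 15 and were not called by camera (adjusted p = 0.0654): JUND (0.64), JUNB (0.57) and IER2 (0.32) rose, and FOSL1 fell by 3.66 ± 0.63 on the log2 scale (-2.39 without Empty 2). In all, 4439 genes were called with ETV1, 2241 higher (395 at least 2-fold) and 2198 lower (351 at least 2-fold), and 1987 without Empty 1, 2706 without Empty 2 and 2601 without ETV1 2. The share that rose was 50.5%, and 40% with library totals.

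**Figure D3:**
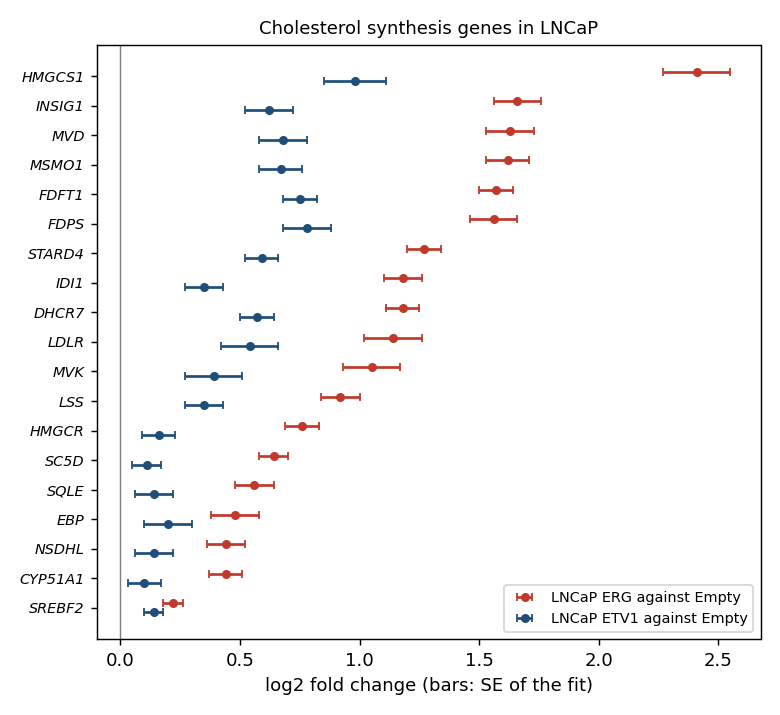
Log2 change of 19 cholesterol synthesis genes in LNCaP with ERG (red) or ETV1 (blue) against the empty vector. Bars are approximate SE (n = 2 libraries per group).

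ERG and ETV1 were also set against each other. Cholesterol synthesis genes were higher with ERG in 17 of 19 and lower in 0, or 18 and 0 adjusted over the list alone, with HMGCS1 by 1.43 ± 0.13, INSIG1 by 1.04, MSMO1 by 0.95 and FDFT1 by 0.82. By camera the adjusted p was 2.94e-26, and adjusted p = 0.258 with an estimated correlation. Androgen receptor targets were higher with ERG than with ETV1 in 15, lower in 1 and uncalled in 12, or 17 and 2 adjusted over the list alone, among them STEAP4 (2.59 ± 0.25), HERC3 (1.54 ± 0.07), ELL2 (0.95) and PMEPA1 (0.63). Camera gave it an adjusted p of 1.23e-11, and adjusted p = 0.258 with an estimated correlation. Genes reported high in ERG-positive tumours were higher in 9, lower in 3 and uncalled in 6, or 11 and 4 adjusted over the list alone, with PLA1A (1.55 ± 0.06), HLA-DMB (1.63 ± 0.08) and CRISP3 (0.99 ± 0.11) higher. For this list the camera adjusted p was 1.37e-09, and adjusted p = 0.147 with an estimated correlation. ADGRF5 was 26.1-fold higher with ERG. TCN1 was 102-fold, MGP 36.6-fold, IL33 16.8-fold (DESeq2 adjusted p = 0.261, and 0.0556 without ETV1 1) and TLE4 13.3-fold lower. IGF2 and INS-IGF2, which share reads, were called higher (5.56 ± 1.54 and 5.59 ± 1.54), with IGF2 at 26 ± 35.6 CPM with ERG. Without ERG 2 they stood at 0.52 (adjusted p = 0.545) and 0.59 (adjusted p = 0.478), and their calls were also lost without ETV1 1 (0.211 and 0.207) or ETV1 2 (0.233 each) and with the compared groups alone in the fit (0.071 and 0.0702).

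Smaller lists were also called between ERG and ETV1: the ETS family with both transgenes, among them ELK4 (0.31) and SPDEF (0.37) (4 higher, 1 lower, 16 uncalled, or 6 and 1 adjusted over the list alone, camera adjusted p = 8.78e-06, adjusted p = 0.147 with an estimated correlation, 0.177 without ERG and ETV1), WNT genes (2 higher, 0 lower, 10 uncalled, adjusted p = 0.0138, adjusted p = 0.258 with an estimated correlation) and stress genes (6 higher, 0 lower, 12 uncalled, adjusted p = 0.0156, adjusted p = 0.431 with an estimated correlation). The BRG1-restored list (4 higher, 0 lower, 7 uncalled, or 4 and 1 adjusted over the list alone) had a camera adjusted p of 0.0271, adjusted p = 0.258 with an estimated correlation, and was lost without ETV1 1 (0.0589) or ETV1 2 (0.0849). In all 2441 genes differed, 1337 higher (245 at least 2-fold) and 1104 lower (155 at least 2-fold) with ERG, but 1471 without ERG 1, 1529 without ETV1 1 and 1003 without ETV1 2. The share higher was 54.8%, and 64.8% with library totals.

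The LNCaP gene sets of ERG and ETV1 overlapped: 1400 genes rose with both and 1305 fell with both, against 344.3 and 314.8 for independent lists, while 40 and 38 went opposite ways (337.7 and 321). ENC1 rose by 3.73 with ERG and 3.81 with ETV1, EML6 by 3.27 and 2.97, the protease gene PRSS23 by 4.17 and 4.07, SLITRK6 by 3.03 and 3.21, REG4 by 5.96 and 4.71 and the bombesin receptor gene GRPR by 3.48 and 2.54. Again part of the excess may come from the shared Empty libraries. With Empty 1 for ERG and Empty 2 for ETV1, 618 rose and 536 fell with both (86.7 and 76.1 for independent lists), and 705 and 563 with these swapped (113 and 86.3). Simulated unchanged groups shared at most 3 calls (mean 0.7), too few to gauge the controls' part. Across genes, which are not independent replicates, r was 0.68 (rho 0.65) against 0.49 ± 0.016 (SD) simulated, and the covariance was 0.352 against 0.0273. The 2705 shared calls became 1197 without Empty 1 and 1588 without Empty 2.

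The ERG responses of VCaP and LNCaP share no library. Of 15567 genes tested in both, 1132 fell with shERG in VCaP and rose with ERG in LNCaP, where 915 would be shared by chance (odds ratio 1.55, 95% interval 1.42 to 1.7, Fisher's exact test, two-sided, p = 1.25e-22). ERG (-2.2 in VCaP, 11.07 in LNCaP), ENC1 (-1.49, 3.73), EML6 (-3.83, 3.27), FZD4 (-2.64, 2.48), GRPR (-1.37, 3.48) and PRSS23 (-0.74, 4.17) were among them. Genes that fell in both lines were also in excess (968 against 859.3, odds ratio 1.26, Fisher's exact p = 4.21e-07). Those that rose in VCaP and fell in LNCaP numbered 662 against 675 (odds ratio 0.968, Fisher's exact p = 0.535), and those that rose in both 711 against 718.7 (Fisher's exact p = 0.717). Across genes r was 0.07 and rho -0.01. The 1132 shared genes became 674 without LNCaP Empty 1 and 742 without Empty 2, and genes are not independent, so that the p describes the overlap of a pair of lists only.

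SW13 cells hold little SMARCA4 or SMARCA2 RNA, and they were used to ask what BRG1 does with and without ERG. With BRG1 in place of GFP and no ERG, SMARCA4 was 69.8-fold higher (6.13 ± 0.1, adjusted p = 5.13e-31), and SMARCA2 went from 0.066 to 1.07 CPM (ratio 16.4, 95% interval 5.35 to 82). The matrix gene SPARC rose 138-fold (7.11 ± 0.16) and the growth factor gene CSF1 66.2-fold. CD44, a hyaluronan receptor, had 3 reads with GFP and 62.9 ± 4.19 CPM with BRG1 (ratio 972, 95% interval 332 to 4710), and SAMD9, with 1 read, a ratio of 3100 (556 to 122000). Against 0 reads with GFP, TGFBI was at least 204-fold higher (26.4 ± 1.46 CPM), KRT75 at least 184-fold, SLCO2A1 at least 176-fold, LAMB3 at least 169-fold, DDX60 at least 119-fold, STRA6 at least 105-fold and SRPX2 at least 98.2-fold. Falls were smaller: EGR1 fell 7.09-fold (-2.83 ± 0.1), the neurotensin gene NTS 7.04-fold (1829 to 260 CPM), ABCD2 5.63-fold, SEMA3D 5.17-fold, PI15 4.82-fold and CDH7 4.63-fold. The glucose transporter genes SLC2A3 and SLC2A14 fell 5.3-fold and 5.28-fold and share reads. ETV1 fell by 0.99 ± 0.07 on the log2 scale, and ARID1A stood at -0.09 (adjusted p = 0.274).

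Interferon-stimulated genes rose as a group with BRG1 in SW13: 25 of 25, also when adjusted over the list alone, with a median log2 change of 6.72, or 5.35 with members at 0 reads set to their bound. IFIT3 rose 878-fold, IFI27 222-fold (7.8 ± 0.15), IFIT1 105-fold (6.72 ± 0.15, 1.22 to 130 CPM) and OAS3, which makes an activator of RNase L, 26.9-fold (4.75 ± 0.1). Camera gave an adjusted p of 4.47e-74, and adjusted p = 0.00486 with an estimated correlation. The BRG1-restored list rose in 11 of 11, alike adjusted over the list alone (camera adjusted p = 2.26e-33, adjusted p = 0.000299 with an estimated correlation). Basal epithelial genes gave 14 rises and 1 fall of 15, alike adjusted over the list alone, with a median of 5.89 (3.79 at the bound), COL17A1 262-fold and S100A2 18-fold higher (camera adjusted p = 5.35e-12, adjusted p = 0.00284 with an estimated correlation). Mesenchymal genes gave 16 rises, 4 falls and 4 uncalled of 24, or 16 and 5 adjusted over the list alone, including TAGLN (14.8-fold) and the collagen gene COL1A1 (13.1-fold) (camera adjusted p = 3.45e-10, adjusted p = 0.00947 with an estimated correlation). Invasion proteases and inhibitors gave 12 rises, 4 falls and 2 uncalled of 18, or 12 and 5 adjusted over the list alone, with the urokinase gene PLAU 16.1-fold and the gelatinase gene MMP2 32.1-fold higher. Its camera adjusted p was 8.38e-07, and adjusted p = 0.0336 with an estimated correlation. Neuroendocrine genes gave 0 rises, 7 falls and 3 uncalled of 10 (median -0.45, camera adjusted p = 0.00245, adjusted p = 0.0448 with an estimated correlation).

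Other list calls with BRG1 against GFP were lost with an estimated correlation. Luminal genes gave 8 rises, 1 fall and 6 uncalled of 15 (camera adjusted p = 0.0041, adjusted p = 0.108 with an estimated correlation, 0.0653 with no filter), and stress genes 11 rises, 1 fall and 6 uncalled (camera adjusted p = 0.011, adjusted p = 0.549 with an estimated correlation). Cell cycle genes gave 3 rises, 19 falls and 6 uncalled (median -0.31, camera adjusted p = 0.019, adjusted p = 0.659 with an estimated correlation, 0.101 without GFP Empty 2). Androgen receptor targets gave 10 rises, 4 falls and 5 uncalled of 19 (median 0.59, or 0.51 at the bound, camera adjusted p = 0.0248, adjusted p = 0.16 with an estimated correlation, 0.175 with no filter, 0.0514 without GFP Empty 2). BAF subunits had a median of -0.16 and a mean of 0.26, SMARCA4 included, and were not called. Adrenal steroidogenesis genes (3 rises, 2 falls, 1 uncalled of 6, camera adjusted p = 0.809) and leukocyte genes (0 rises, 2 falls, 4 uncalled of 6, camera adjusted p = 0.607) were not called here or in any other comparison. Over all genes, 5478 rose and 5137 fell with BRG1, 2168 and 546 at least 2-fold. The share that rose was 51.6%, and 64.1% with library totals, which moved the median of all genes by 0.133.

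**Figure D4:**
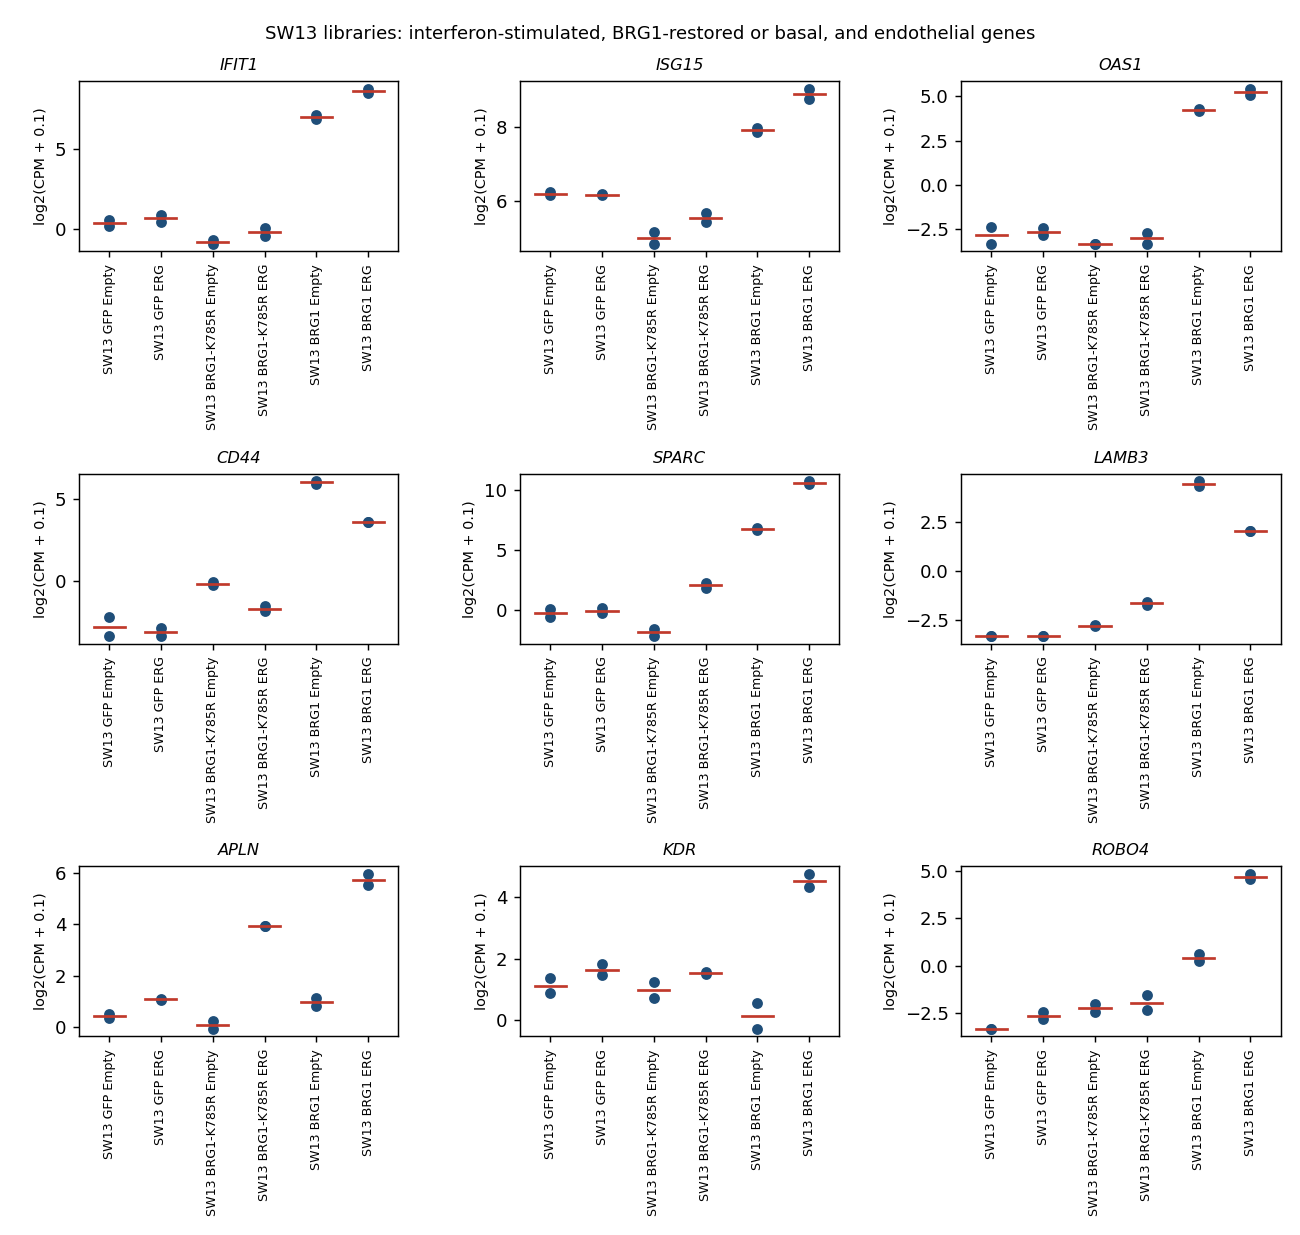
Levels in each SW13 library of interferon-stimulated genes (IFIT1, ISG15, OAS1), BRG1-restored or basal genes (CD44, SPARC, LAMB3) and endothelial genes (APLN, KDR, ROBO4), on the scale log2(CPM + 0.1). Each point is 1 library, and the red line is the mean of the log values of a group (n = 2).

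BRG1-K785R was compared with GFP to ask what BRG1 does without normal ATPase activity. SMARCA4 was 78.5-fold higher (6.29 ± 0.1, adjusted p = 8.06e-31), ARID1A rose by 0.58 ± 0.07, and SMARCA2 had a ratio of 10.1 (95% interval 3.12 to 51.6). RMRP, an RNA of RNase MRP, was 39.7-fold (fitted log2 change 11.38 without GFP Empty 2), ATF3 23.1-fold and AOC2 12.3-fold higher. The aldolase gene ALDOC was 15.6-fold, MALAT1, a nuclear long noncoding RNA, 9.43-fold (862 ± 76.6 to 91.5 CPM, -3.24 ± 0.14), RAB26 9.14-fold and PDK1 8.64-fold lower. Stress response genes gave 15 rises, 1 fall and 2 uncalled of 18 (median 1.17), with TRIB3 (2.75), SESN2 (2.3), the asparagine synthetase gene ASNS (1.83) and DDIT3 (1.82) higher (camera adjusted p = 4.26e-14, adjusted p = 0.123 with an estimated correlation). Ribosomal RNA precursor took 2.308 ± 0.469% (SD, n = 2) of the counts with BRG1-K785R Empty and 0.774 ± 0.679% with GFP Empty (1 at 0.294%, 2 at 1.254%). RMRP went with this share, and polyA selection was not tested. Interferon-stimulated genes gave 2 rises, 7 falls and 16 uncalled of 25, or 1 and 6 adjusted over the list alone (median -0.2, or -0.35 at the bound, camera adjusted p = 0.284).

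Among other lists with BRG1-K785R, neuroendocrine genes gave 1 rise, 6 falls and 3 uncalled, with ENO2 (-1.58), SYP (-1.49), CHGB (-1.64) and UCHL1 (-0.87) lower (camera adjusted p = 0.000404, adjusted p = 0.12 with an estimated correlation). Invasion genes gave 13 rises, 1 fall and 4 uncalled, with PLAU (1.99), MMP2 (2.62), MMP1 (1.15) and TIMP1 (0.59) higher (camera adjusted p = 0.0243, adjusted p = 0.315 with an estimated correlation). BAF subunits, with SMARCA4 counted, gave 12 rises, 6 falls and 12 uncalled of 30 (median 0.02), among them DPF2 (1.22), SMARCD1 (1.03) and ARID2 (0.64) (camera adjusted p = 0.0348, adjusted p = 0.159 with an estimated correlation, 0.324 with no filter, 0.462 without SMARCA4). BRG1-restored genes gave 8 rises, 2 falls and 1 uncalled (median 1.57, camera adjusted p = 0.0479, adjusted p = 0.203 with an estimated correlation, 0.0677 without GFP Empty 1, 0.0593 without BRG1-K785R Empty 2). In all, 9983 genes were called, 5491 higher and 4492 lower, but 1068 and 1209 at least 2-fold. The share higher was 55%, and 47.6% with library totals, and the higher rRNA precursor share stood beside each gene group.

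BRG1 against BRG1-K785R, again without ERG, compared groups whose SMARCA4 levels differed by -0.17 (adjusted p = 0.0517). Beside every gene group here, the rRNA precursor share was 0.511 ± 0.074% with BRG1 and 2.308 ± 0.469% with BRG1-K785R (SD, n = 2). Interferon-stimulated genes were higher with BRG1 in 25 of 25, also adjusted over the list alone (median 6.81, or 5.41 at the bound), among them IFIT3 273-fold, IFIT1 260-fold, IFI27 136-fold and IFI6 42.6-fold. The camera adjusted p was 3.71e-73, and adjusted p = 0.00796 with an estimated correlation. OAS2 was at least 169-fold, OAS1 at least 137-fold and SAMD9L at least 88-fold higher against 0 reads, BST2, the tetherin gene, was 768-fold and SPARC 585-fold higher, and ratios with few reads were 1250 for OASL (223 to 49200), 992 for SAMD9 (339 to 4810), 489 for IGFN1 (167 to 2370) and 488 for LAMB3 (135 to 4030). BRG1-restored genes were higher in 10 and lower in 1 of 11, with CD44 77.2-fold and CSF1 29.7-fold (camera adjusted p = 2.19e-21, adjusted p = 0.00258 with an estimated correlation). Mesenchymal genes gave 15 higher, 6 lower and 3 uncalled, with TGFBI 127-fold, TAGLN 26-fold and COL1A1 15.4-fold higher (camera adjusted p = 1.52e-08, adjusted p = 0.0154 with an estimated correlation). Basal genes gave 13 higher, 1 lower and 1 uncalled, with COL17A1 75.1-fold and S100A2 8.86-fold higher (camera adjusted p = 4.1e-08, adjusted p = 0.00983 with an estimated correlation). RMRP was 67.1-fold, the heme oxygenase gene HMOX1 8.07-fold, CHAC1 5.18-fold, PTGDR2 4.52-fold, SOX5 4.26-fold, TRIB3 4.17-fold, and the read-sharing heat shock genes HSPA1A and HSPA1B 4.31-fold and 4.13-fold lower with BRG1.

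Stress genes were lower with BRG1 than with BRG1-K785R in 14, higher in 2 and uncalled in 2, or 15 and 2 adjusted over the list alone, such as ASNS (-1.75) and TRIB3 (-2.06). By camera the adjusted p was 0.000138, and adjusted p = 0.242 with an estimated correlation. The different rRNA precursor share stood beside these and the further lists. Luminal genes (10 higher, 2 lower, 3 uncalled) had a camera adjusted p of 0.00182 and adjusted p = 0.0739 with an estimated correlation, cell cycle genes (4 higher, 18 lower, 6 uncalled) 0.00683 and adjusted p = 0.671 with an estimated correlation, and invasion genes (10 higher, 6 lower, 2 uncalled) 0.0154 and adjusted p = 0.242 with an estimated correlation, or 0.114 with no filter. BAF subunits were lower in 16, higher in 4 and uncalled in 10, ARID1A at -0.68 ± 0.07 among them (camera adjusted p = 0.0345, adjusted p = 0.116 with an estimated correlation, 0.0687 with library totals). In all, 11345 genes were called, 5545 higher (2672 at least 2-fold) and 5800 lower (697 at least 2-fold). The share higher was 48.9%, and 66% with library totals, with a median shift of 0.213.

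The last question was whether the effect of ERG in SW13 differs with the BRG1 that is present. Beside GFP, ERG was higher by a ratio of 23600 (95% interval 8060 to 114000), and few genes moved far: 4433 were called, 2141 higher and 2292 lower, but 238 and 32 at least 2-fold. MLKL, the necroptosis effector, rose 4.53-fold, FAM43A 4.23-fold (11.5 to 49 CPM, 2.08 ± 0.09), NEK5 3.22-fold, CDC42EP5 2.96-fold, ZNF467 2.85-fold, and TTN, the titin gene, and UNC13A 2.84-fold each. JUN fell 2.59-fold (-1.37 ± 0.12), TNFRSF12A 2.27-fold, NTS 2.26-fold, the protease inhibitor gene TIMP1 2.2-fold (-1.14 ± 0.09), SMIM19 1.97-fold, RGCC 1.91-fold, and CYR61 and ANKRD1 1.9-fold each. ARID1A and ETV1 each rose by 0.4 ± 0.07. Cell cycle genes gave 1 rise, 21 falls and 6 uncalled, or 2 and 25 adjusted over the list alone, with RRM2 (-0.72), BIRC5 (-0.51), CDC6 (-0.48) and MCM7 (-0.36) lower (camera adjusted p = 3.02e-09, adjusted p = 0.596 with an estimated correlation). The ETS family, with ERG counted, gave 3 rises, 0 falls and 16 uncalled of 19, alike adjusted over the list alone: ERG, ETV1 and ETV6 (0.99 ± 0.1) (median 0.07, camera adjusted p = 2.31e-11, adjusted p = 0.0433 with an estimated correlation, 0.0516 with no filter, 0.209 without ERG). AP-1 genes gave 1 rise, 7 falls and 7 uncalled, or 1 and 8 adjusted over the list alone (camera adjusted p = 0.000888, adjusted p = 0.596 with an estimated correlation), with FOSL1 (-0.65), FOS (-0.75) and MAFF (-0.53, adjusted p = 0.0553 without GFP Empty 2 and 0.0625 without GFP ERG 1) lower. Invasion genes gave 0 rises, 5 falls and 13 uncalled, alike adjusted over the list alone, with MMP10 (-0.82), MMP3 (-1.08) and MMP1 (-0.43, but -0.69 without GFP Empty 1 and -0.1 with adjusted p = 0.585 without GFP Empty 2) lower. Camera gave it an adjusted p of 0.0148, and adjusted p = 0.596 with an estimated correlation, 0.102 with no filter, 0.114 without GFP ERG 1. The count of calls was 1743 without GFP Empty 2, 2199 without GFP ERG 1 and 2474 without GFP ERG 2. The share that rose was 48.3%, and 62% with library totals.

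Beside BRG1, ERG (a log2 change of 13.83 ± 0.17) raised endothelial genes in SW13. The apelin gene APLN went from 1.89 to 54 CPM (4.83 ± 0.16), ROBO4 from 1.25 to 25.7 CPM (4.36 ± 0.19), the VEGF receptor gene KDR from 1.04 to 23.6 CPM (4.51 ± 0.22), and TIE1 rose 34.7-fold (5.12 ± 0.29). Of 22 tested endothelial genes 14 rose, 2 fell and 6 were uncalled, alike adjusted over the list alone (median 1.32, camera adjusted p = 3.64e-13, adjusted p = 0.0345 with an estimated correlation). CD93, with 1 read in BRG1 Empty, reached 14.4 ± 2.37 CPM (ratio 784, 95% interval 140 to 31000), EXOC3L2 rose 185-fold, COL15A1 131-fold (a fitted log2 change of 10.92 without BRG1 Empty 1), MYOC 91.8-fold, EXOC3L1 45-fold and HP, the haptoglobin gene, 31.8-fold. SCEL fell 25.4-fold, IGFN1 12.5-fold, KRT75 12.2-fold, COLCA1 11.1-fold, the hemidesmosome collagen gene COL17A1 10.2-fold (-3.35 ± 0.14), CPA4 and ADAMTS15 9.31-fold each and VGF 7.26-fold. Basal genes gave 1 rise, 12 falls and 2 uncalled of 15, alike adjusted over the list alone (median -2.22): CD44 fell from 62.9 to 12.1 CPM (-2.38 ± 0.11) and LAMB3 from 22 to 3.98 (-2.46 ± 0.15), while the integrin gene ITGA6 rose by 0.93 ± 0.08. For this list the camera adjusted p was 1.84e-10, and adjusted p = 0.00873 with an estimated correlation. Interferon-stimulated genes gave 21 rises, 2 falls and 2 uncalled of 25, alike adjusted over the list alone (median 0.98), with IFIT3 from 118 to 466 CPM (1.98 ± 0.09), OASL (2.79 ± 0.11), RSAD2 (2.57 ± 0.12) and IFIT2 (1.79 ± 0.08) higher. Its camera adjusted p was 4.86e-26, and adjusted p = 0.0376 with an estimated correlation.

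Cell cycle genes beside BRG1 gave 0 rises, 26 falls and 2 uncalled with ERG, alike adjusted over the list alone, with MKI67 (-0.89 ± 0.07), E2F1 (-0.82), AURKB (-0.81) and MCM7 (-0.66) lower. The list had a camera adjusted p of 6.34e-11, and adjusted p = 0.276 with an estimated correlation. ERK feedback genes gave 0 rises, 13 falls and 5 uncalled, alike adjusted over the list alone (median -0.62, camera adjusted p = 1.93e-10, adjusted p = 0.106 with an estimated correlation), and AP-1 genes 2 rises, 9 falls and 4 uncalled, alike adjusted over the list alone (median -0.42, camera adjusted p = 0.000133, adjusted p = 0.276 with an estimated correlation). Targets of p53 gave 10 rises, 3 falls and 7 uncalled of 20, alike adjusted over the list alone (median 0.26, camera adjusted p = 0.00921, adjusted p = 0.0966 with an estimated correlation). BRG1-restored genes gave 4 rises, 5 falls and 2 uncalled, alike adjusted over the list alone (median 0.12, camera adjusted p = 0.0115, adjusted p = 0.124 with an estimated correlation, 0.941 with no filter). The ETS family gave 6 rises, 12 falls and 1 uncalled, with a median of -0.3, a mean of 0.3 that ERG itself raises and no call (camera adjusted p = 0.64; without ERG 0.0109, downward, and adjusted p = 0.249 with an estimated correlation). SMARCA4 was at 0 (adjusted p = 0.981), SMARCA2 rose by 1.2 ± 0.3 (adjusted p = 0.0013, DESeq2 adjusted p = 0.0502), ARID1A fell by 0.6 ± 0.07 and ETV1 by 0.21 ± 0.08 on the log2 scale (adjusted p = 0.0203, 0.21 without BRG1 Empty 2, 0.0699 without BRG1 ERG 1 and 0.0845 without BRG1 ERG 2). In all, 7724 genes were called, 3852 higher (666 at least 2-fold) and 3872 lower (647 at least 2-fold). The share higher was 49.9%, and 42.7% with library totals.

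Beside BRG1-K785R, ERG was at least 11300-fold higher and 9563 genes were called, 4309 higher (1300 at least 2-fold) and 5254 lower (614 at least 2-fold). The rRNA precursor share of the counts was 0.404 ± 0.052% with ERG against 2.308 ± 0.469% without (SD, n = 2), and SMARCA4 fell from 2310 to 1370 CPM (-0.76 ± 0.08). RMRP fell 56-fold (13.9 to 0.244 CPM), the chromogranin gene CHGA 11.8-fold, NID1 5.91-fold, TIMP1 5.52-fold (-2.47 ± 0.09), CHAC1 5.06-fold, CRYAB 4.96-fold, ATF3 4.91-fold and TRIB3 4.89-fold (-2.29 ± 0.11). IFITM3 rose 30.2-fold and IFITM2 14.8-fold, a pair that shares reads, APLN 15.8-fold (3.98 ± 0.21), MALAT1 12.3-fold (91.5 ± 3.81 to 1126 ± 186 CPM), RSPO1 9.29-fold, MLKL 7.31-fold and LENG9 5.36-fold. Stress genes gave 1 rise, 15 falls and 2 uncalled, alike adjusted over the list alone (median -0.85), with ASNS (-1.68 ± 0.08), SESN2 (-1.85 ± 0.1) and DDIT3 (-1.25 ± 0.09) lower. The camera adjusted p was 5.33e-11, and adjusted p = 0.271 with an estimated correlation. ARID1A fell by 0.66 ± 0.07 on the log2 scale, and ETV1 rose by 0.51 ± 0.07.

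Cell cycle genes beside BRG1-K785R gave 3 rises, 21 falls and 4 uncalled with ERG, alike adjusted over the list alone, with CDC20 (-1.08), PLK1 (-1.06), UBE2C (-1.12) and MCM5 (-0.81) lower (camera adjusted p = 0.000504, adjusted p = 0.632 with an estimated correlation). Invasion genes gave 2 rises, 10 falls and 6 uncalled, or 3 and 10 adjusted over the list alone, with MMP10 (-1.66), MMP1 (-1.03) and CTSB (-0.76) lower (camera adjusted p = 0.000584, adjusted p = 0.271 with an estimated correlation). AP-1 genes gave 1 rise, 10 falls and 4 uncalled, or 1 and 11 adjusted over the list alone, with FOSL1 (-1.58), JUN (-0.99) and JUND (-0.7) lower (camera adjusted p = 0.00319, adjusted p = 0.589 with an estimated correlation), and ERK feedback genes 1 rise, 12 falls and 5 uncalled, or 1 and 13 adjusted over the list alone (camera adjusted p = 0.00382, adjusted p = 0.589 with an estimated correlation). Interferon-stimulated genes gave 11 rises, 2 falls and 12 uncalled, or 10 and 2 adjusted over the list alone (median 0.69, or 0.54 at the bound, camera adjusted p = 0.0344, adjusted p = 0.698 with an estimated correlation, 0.159 with library totals, 0.0718 without BRG1-K785R ERG 1). The ETS family had a median of -0.17 and a mean of 0.87 and was not called (adjusted p = 0.374). The share of genes that rose was 45.1%, and 64.6% with library totals, a median shift of 0.188, and the different rRNA precursor share stood beside each of these groups.

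The differences between these ERG effects were tested directly. With BRG1 rather than GFP, the ERG effect differed in 6437 genes, 3247 upward (318 at least 2-fold) and 3190 downward (753 at least 2-fold). The share upward was 50.4%, and 37.1% with library totals. APLN had a difference of 4.13, KDR of 3.99 and ENG, the endoglin gene, of 1.79, and endothelial genes were called as a list (6 upward, 1 downward, 15 uncalled, or 5 and 0 adjusted over the list alone, camera adjusted p = 0.0438, adjusted p = 0.658 with an estimated correlation). That call was lost without GFP Empty 1 (0.0758), GFP Empty 2 (0.0522) or BRG1 ERG 2 (0.0948). ERK feedback genes differed downward in 11, upward in 1 and not in 6, or 11 and 2 adjusted over the list alone, with ETV4 (-1.84), SPRED2 (-1.04), ETV5 (-1) and CCND1 (-0.93). Its camera adjusted p was 4.97e-06, and 0.399 with an estimated correlation. The ETS family gave 2 upward, 9 downward and 8 uncalled, or 3 and 9 adjusted over the list alone (camera adjusted p = 0.00972, adjusted p = 0.399 with an estimated correlation), and cell cycle genes 0, 10 and 18, MKI67 (-1.11) among them (camera adjusted p = 0.0335, adjusted p = 0.658 with an estimated correlation, and 0.267 without GFP Empty 1, 0.0577 without GFP ERG 1, 0.0633 without BRG1 Empty 1 and 0.226 without BRG1 ERG 2). Interferon-stimulated genes differed upward in 9, downward in 1 and not in 15 (list not called, camera adjusted p = 0.115). COL17A1 differed by -3.46, but -1.61 without GFP ERG 1.

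With BRG1 rather than BRG1-K785R, the ERG effect differed in 7863 genes, 4390 upward and 3473 downward, but 552 upward and 1453 downward at least 2-fold. The share upward was 55.8%, and 29.9% with library totals (median shift -0.234). Stress genes differed upward in 14, downward in 0 and not in 4, or 15 and 0 adjusted over the list alone, with ATF3 (2.78), TRIB3 (1.81), SESN2 (1.76) and DDIT3 (1.43) (camera adjusted p = 6.61e-12, adjusted p = 0.32 with an estimated correlation). Histones gave 8 upward, 0 downward and 4 uncalled, or 9 and 0 adjusted over the list alone. Its camera adjusted p was 0.0426, and adjusted p = 0.363 with an estimated correlation, 0.0944 without BRG1-K785R Empty 2, 0.0572 without BRG1-K785R ERG 1 and 0.0619 without BRG1 Empty 1. With BRG1-K785R rather than GFP, 6776 genes differed, 2971 upward (686 at least 2-fold) and 3805 downward (580 at least 2-fold). The share upward was 43.8%, and 59.8% with library totals (median shift 0.135). Stress genes differed downward in 11, upward in 1 and not in 6, or 12 and 1 adjusted over the list alone, with TRIB3 (-2.57), SESN2 (-1.99) and ASNS (-1.47). The list had a camera adjusted p of 1.48e-06, and adjusted p = 0.493 with an estimated correlation. Both of these differences use BRG1-K785R Empty, the group with the high rRNA precursor share. For ARID1A, the ERG effect differed by -1.01 ± 0.1 between BRG1 and GFP and by -1.06 ± 0.1 between BRG1-K785R and GFP, and the difference was 0.06 (adjusted p = 0.691) between BRG1 and BRG1-K785R.

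Finally, ERG rises in SW13 with BRG1 were compared with those in LNCaP, which share no library. Of 15466 genes tested in both, 756 rose in both against 542.1 by chance (odds ratio 1.74, 95% interval 1.58 to 1.91, Fisher's exact test, two-sided, p = 3.58e-28). They included ENC1 (1.02 in SW13, 3.73 in LNCaP), FZD4 (1.37, 2.48), the protocadherin gene PCDH12 (2.69, 4.28), APOL3 (4.23, 3.45) and FRMD6 (1.37, 2.67). Genes that fell in both numbered 616 against 512.4 (odds ratio 1.34, Fisher's exact p = 3.14e-08), those that rose in SW13 and fell in LNCaP 556 against 507.8 (odds ratio 1.15, Fisher's exact p = 0.00945), and those with the opposite pattern 518 against 547 (odds ratio 0.921, Fisher's exact p = 0.131). Across genes, which are not independent replicates, r was 0.16 and rho 0.08. The 756 shared rises became 427 without LNCaP Empty 1 and 460 without Empty 2.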

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

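The tests of a virus response and of the share of counts taken by a few genes were chosen only after the results were seen, the verdicts on cells from outside the study and on nuclear RNA were made more cautious after their values were seen, and the library-total and left-out-group alternatives were added then too.

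In LNCaP, 43 genes fell at least 8-fold with both ERG and ETV1, and they were uneven between the Empty libraries. RNA of another line of the study in the Empty libraries is argued against, since the share seen was at most 0.00386 of the share these genes would need. Cells from outside the study stay open: the log2 ratios between the Empty libraries, over 28 of the genes, ran from -3.02 to 3.47, with a spread 7.8 times the counting error. That value passed the bound set beforehand against 1 common source, but the bound was wrong, because the cultures were independent and each could hold a different source. Repression by ETS factors cannot be told apart from it either, since 24 of the genes had a median of -0.39 in VCaP with shERG (7 rose, 10 fell), the 3.16 percentile of 10000 random lists, and another cell line cannot exclude it.

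In SW13 beside BRG1-K785R, ERG went with 9563 calls, including falls of stress genes and a rise of MALAT1, while BRG1-K785R Empty had the highest rRNA precursor share. That share may include mature rRNA. The 10 most abundant genes and the rRNA precursor could shift other genes by a log2 of 0.041 at most. The median called change was 0.57, so they do not explain it. With library totals (median shift 0.188), 7750 calls stayed and 58 turned sign, but 64.6% rose, not 45.1%. Library totals leave composition uncorrected, so a wider shift and small changes stay open. A loss of nuclear RNA in BRG1-K785R Empty met its prediction, with a median of -1.33 (SD 1.25) over 7 nuclear-retained RNAs other than MALAT1, but the members went both ways: NEAT1 (-1.95), KCNQ1OT1 (-1.33), MEG3 (-2.51), OIP5-AS1 (-0.44) and MIAT (-1.95) fell, and TUG1 (0.46) and PVT1 (0.64) rose. It cannot be told apart from an effect of the mutant on transcription, since both BRG1-K785R Empty libraries share the construct and the state. Without that group, calls were 4521 (ERG beside GFP), 7786 (ERG beside BRG1), 10647 (BRG1 against GFP) and 6497 (ERG effect, BRG1 minus GFP).

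Interferon-stimulated genes were higher with BRG1 in SW13. A response to the virus alone is argued against by list medians of -0.2 with BRG1-K785R and 6.72 with BRG1. RNA of another line of the study is argued against by a share of at most 6.8e-05 of what is needed. A response that needs active BRG1, perhaps to the virus all groups received, may be the source. This hypothesis was found and tested on the same data, and interferon itself was not measured.

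The remaining results stand here because the effect of ERG differed between SW13 backgrounds by a test of the difference. These are differences of fitted log2 changes, and where a group had few reads they are no bounds. Between BRG1 and GFP, 6437 genes differed. Upward were RARRES3 (6.42, adjusted p = 0.0801 without GFP Empty 2), IFI44 (6.03, 0.112 without GFP Empty 2), APOL3 (4.29), SGK1 (4.16), APLN (4.13), KDR (3.99), ENG (1.79), CDKN1A (1.58), BTG2 (1.48) and EGFL7 (0.58). Downward were SLCO2A1 (-4.94), IGFN1 (-3.94), ADAMTS15 (-3.64), COL17A1 (-3.46, but -1.61 and adjusted p = 0.572 without GFP ERG 1), ETV4 (-1.84), ETS1 (-1.15), MKI67 (-1.11), SPRED2 (-1.04), ETV5 (-1), CCND1 (-0.93), CENPF (-0.7), BUB1B (-0.51) and E2F1 (-0.46). APOL3 was lost without GFP Empty 1 (0.149), GFP Empty 2 (0.151), GFP ERG 1 (0.0671), GFP ERG 2 (0.0605) or BRG1 Empty 2 (0.0508), and SLCO2A1 with no filter (0.0563), DESeq2 (0.056), the compared groups alone (0.0503) and without GFP Empty 1 (0.11), GFP Empty 2 (0.133), GFP ERG 1 (0.118), GFP ERG 2 (0.116), BRG1 Empty 2 (0.0612) or BRG1 ERG 1 (0.0594).

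Between BRG1 and BRG1-K785R, 7863 genes differed. Upward were APOL3 (5.53, but 1.73 and adjusted p = 0.886 without BRG1-K785R Empty 1), SGK1 (4.79), KIAA1210 (4.64, but 1.39 and 0.862 without BRG1-K785R Empty 1, 0.061 without BRG1-K785R ERG 1 and 8.03 without BRG1-K785R ERG 2), CPA4 (4.56, 0.0628 without BRG1-K785R ERG 1 and 0.0754 without ERG 2), GDF15 (4.29), ATF3 (2.78), MMP2 (1.96), TRIB3 (1.81), CDKN1A (1.81), SESN2 (1.76), BTG2 (1.63), TIMP1 (1.5), DDIT3 (1.43), HIST1H2BK (1.1), MMP10 (1.02), AEN (0.99), HIST1H2AC (0.96), HIST1H2BD (0.92), HIST2H2AA3 (0.91), SMARCA4 (0.76) and CTSB (0.63). Downward were IGFN1 (-6.17), LAMB3 (-4.62) and COL17A1 (-3.68). Between BRG1-K785R and GFP, 6776 genes differed. Upward were RSPO1 (3.9), MALAT1 (3.15), CBR3-AS1 (2.98, an antisense transcript) and PMCH (2.8). Downward were CHAC1 (-2.61), TRIB3 (-2.57), HMOX1 (-2.33), POTEJ (-2.13, a gene with close copies), SESN2 (-1.99), ASNS (-1.47), HIST1H2BC (-1.38), HIST1H4H (-1.33, 0.0865 without GFP ERG 2), TIMP1 (-1.33), HIST1H2BK (-1.32), SPRED2 (-1.11), SMARCA4 (-0.97), MMP10 (-0.84), SPRY4 (-0.79), ETV5 (-0.69), MYC (-0.64), HIST1H2BD (-0.62, 0.0515 with library totals, 0.0751 without GFP Empty 2, 0.0613 without GFP ERG 2), TIMP2 (-0.53) and CTSB (-0.5).

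ERG went with opposite changes in LNCaP and SW13 for some genes, and this difference was not tested. In LNCaP and in SW13 with GFP the log2 changes were -0.28 and 0.4 for ETV1 and -0.29 and 2.08 for FAM43A. In LNCaP and with BRG1-K785R they were -0.49 and 3.98 for APLN, 0.79 and -2.29 for ATF3, 0.49 and -1.25 for DDIT3, -0.28 and 0.51 for ETV1, 1.57 and -0.21 for FDFT1, 2.48 and -0.19 for FZD4, 0.76 and -0.7 for JUND, -2.64 and 0.39 for TPM2 and 1 and -2.29 for TRIB3. In LNCaP and with BRG1 they were -0.49 and 4.83 for APLN, 2.11 and -3.35 for COL17A1, 0.52 and -3.47 for COLCA1, -3.46 and 1.17 for IGFBP4, 7.99 and -3.61 for KRT75 and 4.45 and -2.46 for LAMB3.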

How the results depend on the processing

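Library totals as scale, the SW13 fit without BRG1-K785R Empty, separate controls for overlaps and lists without target genes were chosen after seeing the results. No named gene reversed in any alternative, but library totals switched the larger of rises and falls in most comparisons. The ETS family call for LNCaP ERG turned downward, uncalled, without ERG and ETV1 (0.949), and lists without target genes ended 4 other calls and added 1. Among all called genes library totals turned the sign of 321 for VCaP shERG, 17 for shARID1A against shERG, 58 for SW13 ERG beside BRG1-K785R and 220 for BRG1 against BRG1-K785R. Of the 19 counts of called or shared genes, 12 stayed within 1.5 times their value under every alternative, and the other 7 moved beyond it in 17 of 100 leave-one-out values. With 1 Empty library for each, LNCaP ERG and ETV1 shared 1154 or 1268 calls. Over the single libraries left out, the calls ranged from 2632 to 3873 for LNCaP ERG, 1987 to 3261 for LNCaP ETV1, 1003 to 1638 for ERG against ETV1 and 1743 to 3642 for SW13 ERG beside GFP. The shared calls ranged from 1197 to 2199 for LNCaP ERG and ETV1, 674 to 1085 for VCaP falls and LNCaP rises, and 427 to 687 for SW13 and LNCaP rises. Fewer samples in the fit lower such counts by construction, a group left with 1 library is assumed to vary like the others, and why single libraries differed in their effect was not tested. Of 508 named gene results 471 kept their side of the threshold under all alternatives, and of 330 list tests 220 did, with 77 of the 110 that changed doing so with an estimated correlation. DESeq2 ended 5 named calls, library totals 2, no filter 1 and the fit of the compared groups alone 3. RLE scaling moved no share of rises by more than 3.2 points. Of 33 target levels 8 moved by more than 1 SD with CPM from the library total.

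The replicate number as a block stood for no known pairing, and as a check it gave 4338 calls for LNCaP ERG, 3737 for LNCaP ETV1 and 1783 for ERG against ETV1. It ended the list calls of BAF subunits (0.198) and BRG1-restored genes (0.0543) for BRG1-K785R against GFP, and added 2 others. The ratio of calls with to calls without the block was 0.73 at the lowest and 1 at the highest. Across genes, correlations between groups of the difference between their libraries 2 and 1 ran from -0.01 to 0.04 in VCaP, -0.08 to -0.02 in LNCaP and -0.1 to 0.12 in SW13.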
